A study of Mus musculus with 6 samples.

How the data were processed

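Micrococcal nuclease (MNase) digests the linker DNA between nucleosomes and spares the DNA wrapped around the histones, so that the ends of the released fragments mark nucleosome borders. The series holds 6 libraries of such fragments from primary mouse embryonic fibroblasts, cells grown out of embryos at embryonic day 13.5 on a mixed background of the strains C57BL/6 and 129. Per the labels, Cre recombinase was brought in with a retrovirus and infected cells were selected with puromycin. The 3 genotypes were wild type, Snf5-/- and Brg1-/-. Brg1 (gene Smarca4) is an ATPase found in Swi/Snf chromatin remodelling complexes and Snf5 (gene Smarcb1) is a core subunit of them. Nuclei of each genotype were digested lightly, with 0.2 U of MNase, or moderately, with 4 U. Each of the 6 groups therefore held 1 library, and differences between groups had no replicate check.

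The deposited files list 1 mapped fragment per line, as a chromosome, a start and an end, with no score and no strand. Per the submitters' processing notes, Bowtie was used and the build was mm9. The Bowtie version, the handling of reads with several matches and the treatment of repeated fragments were not given in the sources used here. Per the labels' protocols, DNA of mononucleosome size was selected before PCR, which limits the range of fragment lengths. The deposited fragments were 51 to 500 bp long on 21 chromosomes. Starts and ends were taken as counted from 1 with both included; a file counted another way would move lengths and positions by 1 bp. Libraries carried no molecular identifiers, so counting intervals cover counting error only.

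Fragments with the same start and end were used once, which removed 1.62% to 2.49% of the deposited fragments. Autosomal depth after that step was 7813752, 47039152 and 31040014 fragments for wild type, Snf5-/- and Brg1-/- at light digestion and 30768512, 19278058 and 35996817 at moderate digestion. Counts per window used fragment middles on the 19 autosomes, and densities are fragments per 1000000 autosomal fragments (FPM), with scaled library sizes for the 100 kb bins. The reference table of genes named the assembly GRCm38, another build than that of the fragments, so its coordinates were not used. The comparisons of promoters, transcription start sites, gene lists and motifs planned from the labels were therefore not run. The comparison in 100 kb bins, which had been named as the main one for that case, took their place.

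Bins of 100 kb were compared with limma 3.58.1 (voom) in R 4.3.3, with genotype and digestion as terms and all 6 libraries in the fit. Library sizes were scaled by the median ratio to the mean library. Bins with a mean of at least 5 fragments per library were kept, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The fit left 2 residual degrees of freedom per bin, and its empirical Bayes step drew the variance of each bin towards that of all bins. Its spread is therefore the disagreement of the genotype difference between the digestions, pooled over bins of the same 6 libraries. It is not that between separate cultures. Very small p-values rest on this pooled spread and not on replicates of a bin. The bins named are the 5 with the largest fitted change each way among those past the threshold with the same direction at both digestions, or in all 3 genotypes for the digestion contrast. On simulated data with 200 changed bins among 23913, the Snf5-/- against wild type contrast found 52.5% of 1.5-fold changes and called 3 unchanged bins. Among 23915 bins it found 99% of 2-fold changes and called 13 unchanged bins. In the same simulations the digestion contrast found 82% and 100% and called 13 and 17 unchanged bins. These simulations assumed a dispersion of 0.01 in every library and put no change in bins with few fragments. Their values therefore do not describe bins with few fragments or libraries of unequal spread.

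Nucleosome spacing was the slope of peak position on peak number over peaks 1 to 6 in the histogram of distances between fragment starts up to 1.5 kb. Arrays were measured around strongly positioned nucleosomes, defined as 31 bp windows with at least 6 middles of fragments of 130 to 180 bp and at least 5 times the local mean, kept at least 2 kb apart. They were picked in the mutant left out of each comparison, and the amplitude was the peak of the neighbouring nucleosome minus the mean of the gaps on its sides, relative to the density 1500 to 2000 bp away. Windows of 1 kb that were enriched at light digestion were the 10000 with the largest excess in 1 genotype, measured in the other genotypes. Segments nearly without fragments were runs of at least 2 windows of 1 kb in which a genotype had at most 10% of the fragments due from the lower density of the others, with at least 8 due per window. Standard errors of spacing, arrays, windows and length shares came from leaving out each of the 19 autosomes in turn, and 95% intervals cover counting error and the choice of chromosome only. Counts of single windows have exact Poisson 95% intervals, and ratios of fragments in single bins have exact binomial 95% intervals.

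The spacing estimate was tested on simulated starts with 3 known repeats, with a largest error of 1.07 bp. The light against moderate comparison was tested on 2315857 simulated windows. Without a difference its ratios ran from 0.993 to 1.00, and 14.3%, 36.3% and 43.2% of doubled windows were found at the depths of wild type, Snf5-/- and Brg1-/-. The search for segments, tested on 2315857 simulated windows, found 186 of 200 deletions and 0 segments where none had been put in.

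The bin, spacing and deletion comparisons, their settings and their first alternatives were chosen before the data were examined. The array, light-enriched window, nearly empty segment and fragment length comparisons were chosen after the data had been seen. Alternatives covered repeated fragments, bin and window size, scaling, filters, depth, the range of peaks, the choice of anchors, length borders and leaving out each library. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.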

Results

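To examine how loss of a Swi/Snf subunit changes nucleosomes in fibroblasts, MNase fragments were collected from wild type, Snf5-/- and Brg1-/- mouse embryonic fibroblasts at light and moderate digestion. Each of the 6 combinations held 1 library, with 8225010, 49369094 and 32839886 deposited fragments at light digestion for wild type, Snf5-/- and Brg1-/-, and 32542512, 20268110 and 38132457 at moderate digestion. The median 100 kb bin held 310, 1838 and 1264 distinct fragments at light digestion and 1086, 752 and 1397 at moderate digestion.

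The targeted genes were examined first, as a check of the genotypes. In the 1 Mb of chromosome 10 from 75 to 76 Mb, where Smarcb1 lies by general knowledge, the 2 kb window with the strongest loss in Snf5-/- ran from 75382501 to 75384500 (mm9). It held 26.3% of the lower density of the other genotypes. At light digestion it had 0.213 fragments per 1000000 autosomal fragments (FPM) in Snf5-/- (exact Poisson 95% interval 0.102 to 0.391), against 2.18 (1.27 to 3.48) in wild type and 0.838 (0.547 to 1.23) in Brg1-/-. At moderate digestion the density was 0.156 (0.0321 to 0.455) in Snf5-/-, 1.01 (0.685 to 1.43) in wild type and 0.667 (0.427 to 0.992) in Brg1-/-. On chromosome 9 from 21 to 22 Mb, where Smarca4 lies, the window from 21468501 to 21470500 held 11.3% in Brg1-/-. It had 3 fragments at light and 7 at moderate digestion in Brg1-/-, against 11 and 40 in wild type and 70 and 34 in Snf5-/-. Regions with a loss as strong were found elsewhere: these windows ranked 72 of 1873 and 71 of 1930 regions of 1 Mb. The position of the deleted segments was not given in the labels and no annotation of this build was used, so the check is weak.

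**Figure D1:**
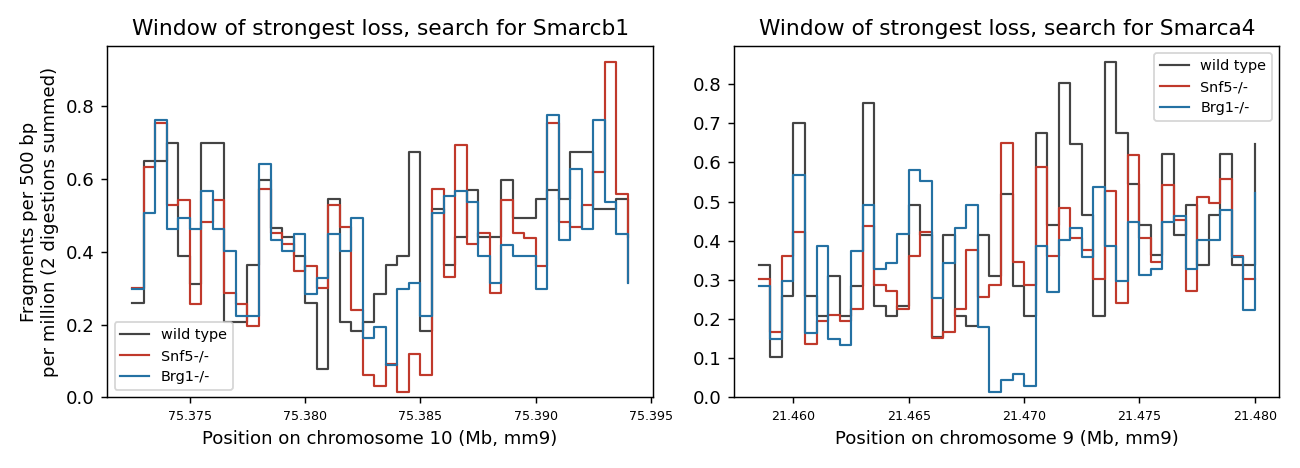
Fragments per 1000000 (FPM) in 500 bp steps, both digestions summed, against position (Mb, mm9) around the windows with the strongest loss in the regions searched for Smarcb1 and Smarca4, with 1 line per genotype. The windows with the strongest loss held 26.3% in Snf5-/- and 11.3% in Brg1-/- of the lower density of the other genotypes.

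Stronger digestion trimmed the fragments to the nucleosome core in all 3 genotypes. At light digestion the most frequent length was 161 bp in wild type, 162 bp in Snf5-/- and 164 bp in Brg1-/-, and at moderate digestion it was 147 bp in each, the length of DNA on a core particle. The share of fragments of 160 to under 180 bp fell by 20.8 percentage points in wild type (SE 0.146), fell by 25.7 in Snf5-/- (SE 0.0647) and fell by 24.1 in Brg1-/- (SE 0.110). Fragments under 120 bp rose from 2.43% to 7.10% in wild type, from 1.56% to 7.56% in Snf5-/- and from 1.67% to 7.14% in Brg1-/-. At moderate digestion smaller peaks, each the highest of 9 neighbouring lengths after smoothing over 3 bp, lay at 92 bp in all 3 genotypes, at 134 bp in wild type and Snf5-/- and at 106, 113 and 135 bp in Brg1-/-. At 113 bp the unsmoothed share stood above both adjacent lengths in all 3 genotypes, at 0.326% in wild type, 0.312% in Snf5-/- and 0.285% in Brg1-/-.

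Mutants kept more fragments of 160 to under 180 bp than wild type at light digestion and fewer at moderate digestion. At light digestion 39.6% of Snf5-/- and 37.2% of Brg1-/- fragments were 160 to under 180 bp long, against 35.3% in wild type, differences of 4.29 (SE 0.150) and 1.89 (SE 0.166) percentage points. At moderate digestion the shares were 13.9% and 13.1% against 14.5%, differences of -0.686 (SE 0.0557) and -1.42 (SE 0.0778) percentage points. With class borders lower by 5 bp, the Brg1-/- difference at light digestion turned to -0.683 percentage points, the same direction as the -1.30 at moderate digestion with those borders. In Snf5-/- the light difference was 2.41 with those borders and 5.83 with borders higher by 5 bp. Its moderate difference was -1.08 and -0.300.

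**Figure D2:**
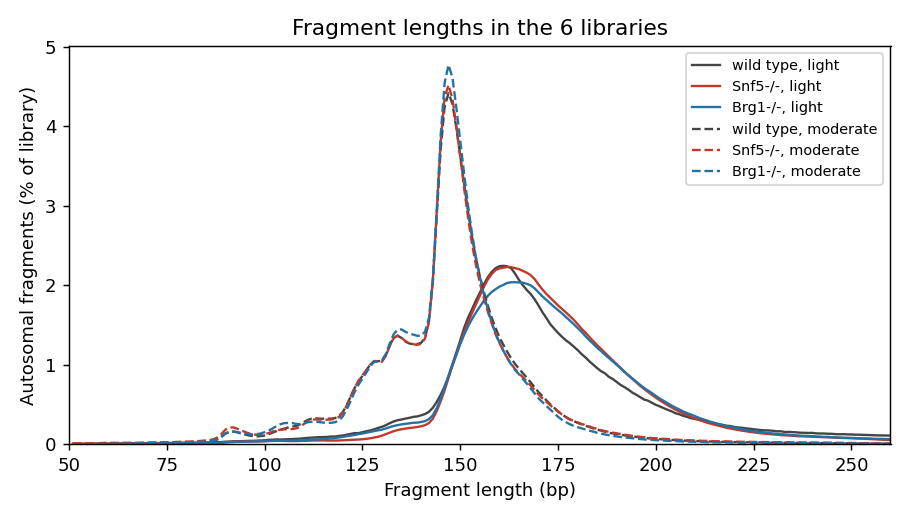
Share of distinct autosomal fragments (percent) against fragment length (bp) for the 3 genotypes at light and moderate digestion. The most frequent length moves from 161 to 164 bp at light digestion to 147 bp at moderate digestion.

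Repeat lengths of the mutants differed from that of wild type by less than 1 bp on peaks 1 to 6 without repeated fragments, though other settings gave larger differences. The repeat length was 187.8 bp in wild type (SE 0.847), 187.3 bp in Snf5-/- (SE 0.120) and 187.8 bp in Brg1-/- (SE 0.166) at light digestion. At moderate digestion it was 187.7 (SE 0.212), 187.6 (SE 0.216) and 188.4 bp (SE 0.126). Differences of Snf5-/- from wild type were -0.539 bp at light digestion (95% interval -2.20 to 1.12) and -0.0168 bp at moderate digestion (-0.435 to 0.402). Brg1-/- differed by 0.00145 bp at light (-1.66 to 1.66) and by 0.716 bp at moderate digestion (0.319 to 1.11). The last difference was 2.03 bp (1.68 to 2.39) on peaks 1 to 4 and 2.32 bp (1.68 to 2.96) without dense windows. It was -0.0785 bp (-1.55 to 1.39) with libraries thinned to 1 depth, 0.0572 bp (-0.463 to 0.578) with repeated fragments kept and 0.222 bp (-2.29 to 2.73) on positions with 2 or more fragments. Snf5-/- at moderate digestion differed by 1.57 bp (1.26 to 1.88) on peaks 1 to 4 and by 1.69 bp (0.815 to 2.56) without dense windows. With repeated fragments kept, the differences at light digestion were -23.7 bp in Snf5-/- (-37.1 to -10.3) and -23.9 bp in Brg1-/- (-38.9 to -8.91), and the repeat lengths themselves had SEs of 5.70 to 22.3 bp.

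Nucleosome arrays around nucleosomes picked in a mutant stood out more sharply in both mutants than in wild type, and in Brg1-/- at moderate digestion this depended on where the nucleosomes were picked. Around 390390 positioned nucleosomes picked in Brg1-/- libraries, the amplitude of the first neighbour at light digestion was 0.660 in Snf5-/- against 0.523 in wild type, a difference of 0.137 (SE 0.00761, 95% interval 0.122 to 0.151). At moderate digestion it was 0.539 against 0.452, a difference of 0.0868 (SE 0.00404, 0.0789 to 0.0948). Around 375117 positioned nucleosomes picked in Snf5-/- libraries, Brg1-/- reached 0.710 against 0.560 at light digestion, a difference of 0.150 (SE 0.00727, 0.136 to 0.164). At moderate digestion it reached 0.499 against 0.459, a difference of 0.0406 (SE 0.00429, 0.0322 to 0.0490). Neighbours 2 to 5 were also sharper, by 0.0419 and 0.050 in Snf5-/- and by 0.0399 and 0.0271 in Brg1-/- at light and moderate digestion. Because anchors came from the other mutant, an array shared by the mutants and absent from wild type would be favoured. Around 145475 nucleosomes picked in wild type the amplitudes were 0.593 in Snf5-/- and 0.603 in Brg1-/- at light digestion, with 0.498 and 0.454 at moderate digestion. In the same places wild type itself, measured where it was picked, had 0.509 and 0.444. These differences were 0.0843 (95% interval 0.0675 to 0.101) and 0.0540 (0.0398 to 0.0682) in Snf5-/- and 0.0943 (0.0723 to 0.116) and 0.0103 (-0.00252 to 0.0230) in Brg1-/-, the last within its error. There neighbours 2 to 5 were sharper by 0.0233 (SE 0.00597) and 0.0421 (SE 0.00323) in Snf5-/- and by 0.0200 (SE 0.00651) and 0.0189 (SE 0.00317) in Brg1-/-. With anchors pooled from all libraries the first-neighbour difference of Brg1-/- at moderate digestion was 0.0241 (0.0170 to 0.0312).

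**Figure D3:**
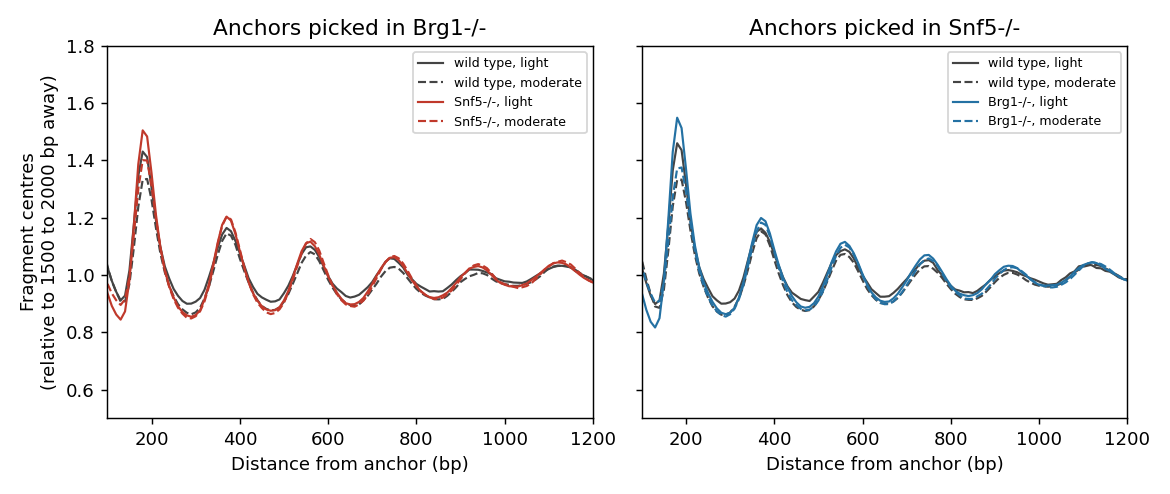
Density of fragment middles relative to the flank against distance (bp) from positioned nucleosomes picked in the mutant left out, at light and moderate digestion. The first neighbour has an amplitude of 0.660 in Snf5-/- against 0.523 in wild type, and of 0.710 in Brg1-/- against 0.560, at light digestion.

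Distances between all fragment starts also gave sharper arrays in both mutants than in wild type. The first peak of the distance histogram was 1.09 times its running mean (SE 0.00158) in Snf5-/- and 1.09 times (SE 0.00172) in Brg1-/- at light digestion, against 1.05 times (SE 0.00296) in wild type. At moderate digestion the heights were 1.08 (SE 0.00112), 1.06 (SE 0.000863) and 1.05 (SE 0.00112).

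Light digestion yielded relatively more fragments than moderate digestion in a set of 1 kb windows, and these windows were partly shared between genotypes. The 10000 windows most enriched at light digestion in Brg1-/- had a light to moderate ratio of 1.93 in wild type (95% interval 1.86 to 1.99) and 1.83 in Snf5-/- (1.77 to 1.88). Windows picked in Snf5-/- had a ratio of 1.63 in wild type (1.58 to 1.67) and 1.69 in Brg1-/- (1.66 to 1.73). Windows picked in wild type gave 1.31 in Snf5-/- (1.26 to 1.35) and 1.55 in Brg1-/- (1.502 to 1.60). Their size depended on depth and on the number of windows: those picked in Brg1-/- gave 1.32 and 1.31 with libraries thinned to 1 depth and 2.48 and 2.44 with 2000 windows, in wild type and Snf5-/-. Those picked in Snf5-/- gave 1.22 and 1.26 when thinned and 2.07 and 2.27 with 2000 windows, in wild type and Brg1-/-. At light digestion, windows picked in wild type held 0.714 (Snf5-/-) and 0.717 (Brg1-/-) times the mean density, or 1.23 and 1.24 when thinned. Those picked in Snf5-/- held 1.87 (wild type) and 1.77 (Brg1-/-), and those picked in Brg1-/- held 1.60 (wild type) and 1.57 (Snf5-/-). Ratios, overlaps and chromosomes of the wild type set therefore compare unlike windows. Snf5-/- and Brg1-/- shared 2071 windows where independent lists would share 54.6, and all 3 genotypes shared 324 where independent lists would share 0.357. Independent lists take every window as equally likely to be picked. The ranking favours windows with many fragments, and the sets picked in the mutants were dense, so part of this overlap may come from shared density. Among windows enriched at moderate digestion, all 3 genotypes shared 8, where independent lists would share 0.357.

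The window shared at the top lay on chromosome 17 from 56218001 to 56219000. It held 2.30, 2.34 and 2.00 FPM at light digestion in wild type, Snf5-/- and Brg1-/-, against 0.163, 0.311 and 0.194 at moderate digestion. A window on chromosome 7 from 20301001 to 20302000 held 2.30, 1.89 and 1.74 against 0.163, 0.259 and 0.389. The moderate values rest on 5, 6 and 7 fragments on chromosome 17 and on 5, 5 and 14 on chromosome 7. Both windows were ranked by these same counts, so the size of their contrast follows from the choice. Windows enriched at light digestion were densest on chromosome 7, with 9.95 per 1000 usable windows when picked in Snf5-/- and 10.2 when picked in Brg1-/-, while those picked in wild type were densest on chromosome 3, with 6.80. Inside windows picked in Brg1-/-, 42.2% of wild type and 42.2% of Snf5-/- fragments at light digestion were 180 bp or longer, against 32.3% and 32.5% over usable windows. The share under 120 bp was also higher there, at 3.92% against 2.24% in wild type and 3.18% against 1.53% in Snf5-/-.

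Mutants differed from wild type by small factors in these windows. Relative to wild type, the density of Snf5-/- in windows picked in Brg1-/- was 0.982 at light digestion (95% interval 0.971 to 0.994) and 1.04 at moderate digestion (1.02 to 1.05). The light value turned to 1.01 with libraries thinned to 1 depth, and the moderate value to 0.986 with 2000 windows. Brg1-/- had 0.947 of the wild type density at light digestion (0.936 to 0.958) and 0.909 at moderate digestion (0.898 to 0.919), in windows picked in Snf5-/-. In windows picked in wild type, Brg1-/- had 1.00 times the density of Snf5-/- at light digestion (0.993 to 1.01) and 0.847 times at moderate digestion (0.834 to 0.860), or 0.981 times when thinned.

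**Figure D4:**
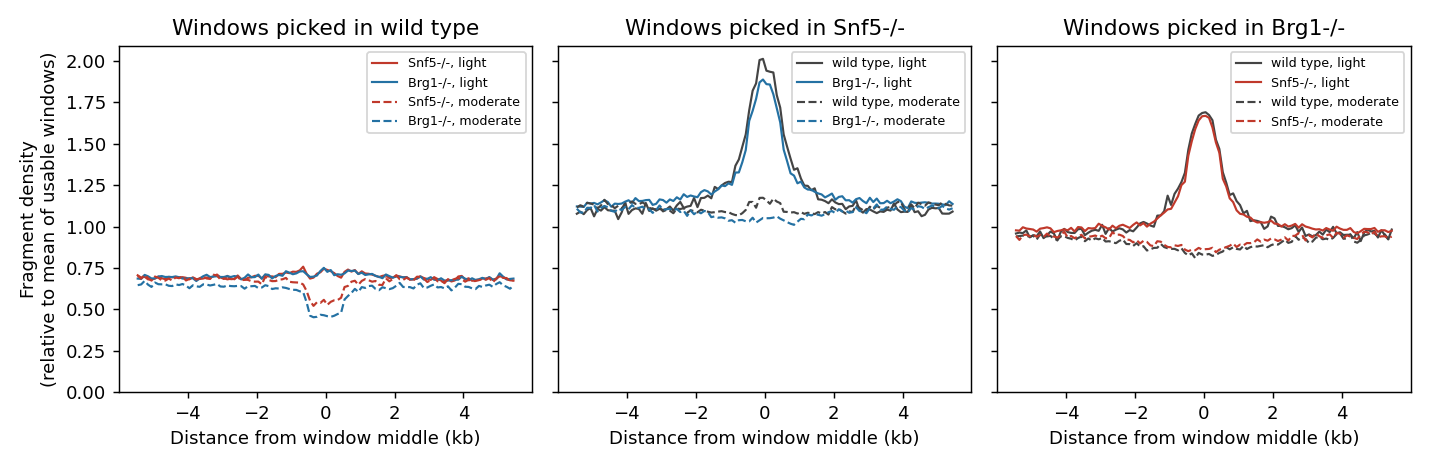
Fragment density relative to the mean of usable windows against distance (kb) from the middle of the 10000 windows enriched at light digestion, with 1 panel per genotype in which they were picked and lines for the other genotypes. Solid lines are light and dashed lines moderate digestion; the light to moderate ratio is 1.93 in wild type for windows picked in Brg1-/-.

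Snf5-/- libraries differed from wild type in 308 of 23912 bins of 100 kb, which measure fragment density over large regions. At a limma adjusted p of 0.05, 163 were higher and 145 lower in Snf5-/-. Over all bins the wild type libraries were less alike (correlation 0.970) than those of Snf5-/- (0.993) or of Brg1-/- (0.989). Wild type at light digestion had correlations of 0.971 to 0.981 with the mutant libraries. Each contrast with wild type rests on these unlike controls, in a fit that takes the libraries to vary alike. The strongest loss lay on chromosome 13 from 61900001 to 62000000, with a log2 change of -3.87 (SE 0.20, adjusted p = 5.63e-77). It held 13.2 and 14.0 FPM in wild type at light and moderate digestion, 0.859 and 1.02 in Snf5-/- and 6.86 and 6.37 in Brg1-/-. The next bins on either side, starting at 62000001 and 61800001, had log2 changes of -3.04 and -1.96. Chromosome 4 from 121700001 to 121800000 was higher, by 2.55 on the log2 scale (SE 0.22, adjusted p = 1.98e-26). The remaining bins named as higher lay on chromosome 5, starting at 95400001, 94700001, 95300001 and 94900001, with log2 changes of 3.46, 3.32, 3.30 and 3.11. They held few fragments: the first had 46 in Snf5-/- and 1 in wild type, a ratio of 25.2 (exact 95% interval 4.31 to 1018), and the third had 61 and 4, a ratio of 8.36 (3.10 to 31.7). The remaining bins named as lower began at 68600001 on chromosome 13 and at 23600001 on chromosome 7, with -1.62 and -1.61. Of the 308 bins, 294 had the same direction at both digestions, against 34.3% of all bins, and the fit itself favours bins in which the digestions agree. The median absolute change was 0.47 on the log2 scale. Without the median-ratio scaling 56 bins were higher and 32 lower, and with quantile normalization 123 and 209. The count without 1 library was 9016 (wild type, light), 1879 (Snf5-/-, light), 133 (Brg1-/-, light), 635 (wild type, moderate), 86 (Snf5-/-, moderate) and 160 (Brg1-/-, moderate). A fit without a library leaves its genotype with a lone library, which was assumed to vary like the others.

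Brg1-/- libraries differed from wild type in 563 bins, of which 276 were higher and 287 lower. On chromosome 17 the bin from 40100001 to 40200000 was higher by 4.38 on the log2 scale (SE 0.24, adjusted p = 7.56e-70). It held 11.7 and 11.1 FPM in Brg1-/- against 0.874 and 0.381 in wild type and 0.314 and 0.665 in Snf5-/-. Its neighbour from 40200001 was higher by 3.30. The chromosome 4 bin from 121700001 was higher here too, by 3.47 (SE 0.22, adjusted p = 1.63e-54), with its neighbour from 121600001 at 2.79, and the chromosome 5 bin from 95300001 at 2.60 from 40 fragments in Brg1-/- against 4, a ratio of 5.48 (1.98 to 21.1). Among the lower bins, chromosome 12 from 116800001 to 116900000 had a log2 change of -1.88 (SE 0.11, adjusted p = 1.79e-62). Its density was 62.8 and 59.1 FPM in wild type, 16.9 and 16.4 in Brg1-/- and 37.2 and 42.5 in Snf5-/-. Chromosome 7 from 67800001 had -2.25, and bins starting at 68600001 on chromosome 13, 9900001 on chromosome 7 and 61200001 on chromosome 4 had -1.77, -1.58 and -1.57. The chromosome 7 bin from 9900001 rests on 9 fragments in Brg1-/- against 13 in wild type, a ratio of 0.380 (0.143 to 0.960). Without their 10 fullest windows of 1 kb, the chromosome 4 bin from 61200001 had a log2 change of -0.11 and the chromosome 5 bin from 95300001 had 1.203. Of the 563 bins, 549 had the same direction at both digestions, against 50.2% of all bins, with a median absolute change of 0.38. Without the median-ratio scaling 489 bins were higher and 105 lower. The count without 1 library was 2771 (wild type, light), 108 (Brg1-/-, light), 3409 (wild type, moderate) and 81 (Brg1-/-, moderate).

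Smaller differences from wild type were repeated between the digestions in part. Over all bins, which are not independent replicates, the Snf5-/- minus wild type difference at light digestion had a correlation of -0.0456 with that at moderate digestion, the Brg1-/- minus wild type difference 0.282 and the Snf5-/- minus Brg1-/- difference 0.572. Bins at 0.25 to 0.5 on the log2 scale between Snf5-/- and wild type at light digestion had a slope of moderate on light of -0.243 (bootstrap 95% interval -0.283 to -0.203), with the same sign in 30.2% of them, against 0.192 (0.178 to 0.207) and 64.5% in Brg1-/-. Bins at 0.5 to 1 had slopes of 0.455 (0.350 to 0.568) in Snf5-/- and 0.411 (0.369 to 0.457) in Brg1-/-, with the same sign in 69.9% and 83.2%. Bins over 1 had slopes of 0.774 (0.549 to 0.987) in Snf5-/- and 0.863 (0.666 to 1.05) in Brg1-/-, with the same sign in 79.5% and 100%. Between Snf5-/- and Brg1-/- the slope was 0.882 (0.842 to 0.922) at 0.25 to 0.5 and 0.953 (0.856 to 1.04) at 0.5 to 1. Over 1 it was 0.906 (0.836 to 0.996). All these bins were picked by their light value, so error in that value shrinks the slopes. The digestion difference itself varied more over bins in wild type, with an SD of 0.332 on the log2 scale, than in Snf5-/- (0.106) or Brg1-/- (0.159).

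The mutants shared 79 higher and 84 lower bins, where independent lists would share 1.88 and 1.74, and 1 bin went opposite ways. Over all bins their differences from wild type had a correlation of 0.575, against 0.536 in 20 simulations without any change. In these all 6 libraries were drawn around bin means pooled over the libraries, with an assumed dispersion of 0.01 in each. The covariance was 0.0167 against a simulated 0.0138. Equal spread leaves out that the digestion difference varied more in wild type than in the mutants. These values therefore do not show a change shared by the mutants. With 1 wild type library per digestion the controls could not be split, so part of the overlap may come from the shared controls.

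Compared directly, the mutants differed in 113 bins, 80 higher and 33 lower in Snf5-/- than in Brg1-/-. Lower bins were those of chromosome 17 from 40100001 (log2 change -4.71, SE 0.28, adjusted p = 1.41e-60) and 40200001 (-4.33), chromosome 13 from 61900001 (-2.82) and 62000001 (-1.995), and chromosome 17 from 13500001 (-1.83). Among the higher bins, chromosome 5 from 15000001 to 15100000 had a log2 change of 1.51 (SE 0.16, adjusted p = 9.73e-19), and chromosome 7 from 111400001 had 1.53. Those starting at 113200001 on chromosome 7, 6700001 on chromosome 17 and 94800001 on chromosome 5 had 2.52, 1.52 and 1.34, the first from 57 fragments in Snf5-/- against 8, a ratio of 7.13 (3.38 to 17.3). All fragments of the chromosome 17 bin from 6700001 in both mutants lay in its 10 fullest windows of 1 kb. Of the 113 bins, 112 had the same direction at both digestions, against 63.5% of all bins. With quantile normalization 64 bins were higher and 61 lower. The count without 1 library was 1793 (wild type, light), 1112 (Snf5-/-, light), 35 (Brg1-/-, light), 868 (wild type, moderate), 46 (Snf5-/-, moderate) and 38 (Brg1-/-, moderate).

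Moderate digestion lowered the share of fragments in 564 bins and raised it in 40. Chromosome 7 held 213 of the 564 lower bins, with 1387 of the 23912 bins tested. The longest run of lower bins covered 24 bins on chromosome 7 from 97500001 to 99900000. Chromosome 1 from 24600001 to 24700000 had a log2 change of -1.27 (SE 0.08, adjusted p = 2.87e-58), falling from 133 to 34.2 FPM in wild type, from 52.6 to 43.8 in Snf5-/- and from 45.9 to 29.6 in Brg1-/-. Chromosome 2 from 22400001 had -1.07 (SE 0.08, adjusted p = 1.39e-32). The other bins named as lower, starting at 10000001 on chromosome 7, 176600001 on chromosome 2 and 121800001 on chromosome 4, had -1.37, -1.06 and -0.90. Bins named as higher changed less: those starting at 42900001 on chromosome 14, 28100001 on chromosome 17, 125100001 on chromosome 5, 6800001 on chromosome 19 and 3000001 on chromosome 3 had 0.71, 0.63, 0.48, 0.45 and 0.44. Of the 604 bins, 557 had the same direction in all 3 genotypes, as did 43.5% of all bins, and the median absolute change was 0.30. Over all bins, which are not independent, the change in wild type had a correlation of 0.0694 with that in Snf5-/- (same sign in 50.5%) and of 0.672 with that in Brg1-/-, and the mutants had 0.314. Only 2 of the 10 bins named here stayed called in the alternatives on 100 kb bins that tested them and without each library. The check without the 10 fullest windows of 1 kb was run only for the genotype contrasts. Fragments piled up in a few windows were therefore not tested for in these bins. With quantile normalization 785 bins were higher and 1165 lower. The count without 1 library was 2217 (Snf5-/-, light), 11 (Brg1-/-, light), 1270 (wild type, moderate), 1671 (Snf5-/-, moderate) and 12 (Brg1-/-, moderate).

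Each genotype lacked fragments in short segments that the other genotypes filled. Wild type had 30 such segments (78 kb), Snf5-/- 36 (85 kb) and Brg1-/- 55 (134 kb). The counts are not comparable: the 8 fragments due per window are reached less often at the lower summed depth of wild type. In that order, 30, 35 and 55 of the segments held at most 25% of the fragments due at each digestion. A rule on the summed digestions favours this. The longest lay on chromosome 8 from 52409001 to 52416000, with 0 fragments in Brg1-/- where the lower density of the other genotypes gave 118. In Snf5-/- chromosome 8 from 125950001 to 125954000 held 2 fragments where 133 were due, and in wild type chromosome 14 from 66090001 to 66095000 held 1 where 119 were due. Of the 36 segments of Snf5-/- 9 lay on chromosome 8, as did 13 of the 55 of Brg1-/-. Segments of any genotype lay in 5.19% of the bins that differed between Snf5-/- and wild type and 4.62% of those between Brg1-/- and wild type. They lay in 10.6% of those between the mutants, against 0.431% of all bins. Segments and bins were found in the same counts, so fragments missing in a genotype can enter both. Wild type segments rose to 60 with a limit of 20%.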

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

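The tests in this part were chosen only after the result was seen, except that of fragments piled up on the Y chromosome.

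The length difference between mutant and wild type changed with digestion. The share of fragments of 160 to under 180 bp, mutant minus wild type, was higher at light than at moderate digestion by 4.97 percentage points in Snf5-/- and by 3.31 in Brg1-/-. With class borders lower by 5 bp these values were 3.49 and 0.614, and with borders higher by 5 bp 6.13 and 5.52. The difference went opposite ways at the digestions in both mutants, except that with the lower borders Brg1-/- was below wild type at both, by -0.683 and -1.30. With 1 library per group this was not tested between cultures.

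Y chromosome fragments entered no comparison above and were most frequent in Snf5-/-, with 543 per 1000000 autosomal fragments at light digestion (exact Poisson 95% interval 536 to 550) and 643 at moderate digestion (632 to 654), against 219 and 171 in wild type and 11.3 and 8.78 in Brg1-/-. Fragments piled up in a few windows did not account for it: without the 10 fullest windows of 10 kb, Snf5-/- still exceeded wild type 2.21-fold at light and 3.35-fold at moderate digestion. The X chromosome share was lower in Snf5-/- than in Brg1-/-, with a ratio of 0.780 (0.778 to 0.782) at light and 0.828 (0.826 to 0.831) at moderate digestion, while Snf5-/- over wild type was 0.801 and 0.928 and wild type over Brg1-/- 0.974 and 0.892. All lay below 1, but sizes did not track the Y chromosome, on which Snf5-/- exceeded wild type 2.48-fold at light and 3.76-fold at moderate digestion. The direction of these ratios is consistent with a larger share of male embryos among the Snf5-/- cells, a hypothesis found and tested on the same data, and the sex of the embryos was not given in the labels.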

How the results depend on the processing

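Leaving out a library, 1 Mb bins, repeated fragments, positions with 2 or more fragments and peaks 1 to 4 were planned; the tests under all other settings in this part were chosen only after the result was seen. Alternatives for promoters, start sites, motifs, gene lists and GC content were not run, for want of an annotation of this build, nor were edgeR and DESeq2, which had been planned only for files whose values are counts. For each value below the cause was not tested, except where bin size set the number of bins tested or thinning set the depth.

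Bins that differed numbered, for Snf5-/- against wild type, Brg1-/- against wild type, Snf5-/- against Brg1-/- and the digestions, 16, 37, 5 and 46 with 1 Mb bins and 536, 1102, 442 and 2361 with 10 kb bins, as fewer or more bins were tested. With limma-trend they numbered 97, 155, 59 and 245, and with libraries thinned to 1 depth 74, 120, 46 and 138. Bins at 0.25 to 2 times the mean density gave 143, 321 and 72 for the genotype contrasts. Without the scaling there were 88 for Snf5-/- against wild type, 60 for Snf5-/- against Brg1-/- and 328 for the digestions, and quantile normalization gave 1950 for the digestions. Leaving out 1 library gave 86 to 9016, 81 to 3409, 35 to 1793 and 11 to 2217. Of 60 counts of bins 16 stayed within 1.5 times. Of 476 values of named bins, 419 kept direction and side of the threshold, 57 kept direction but missed it and 0 reversed. Of the 10 bins named per contrast, 9, 9, 8 and 2 stayed called in every alternative on 100 kb bins that tested them and without each library.

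Spacing for wild type, Snf5-/- and Brg1-/- at light and then at moderate digestion was 185.7, 186.0, 187.0, 185.1, 186.7 and 187.1 bp on peaks 1 to 4, and 217.7, 194.0, 193.8, 202.8, 211.0 and 202.9 bp with repeated fragments. It was 205.3, 187.9, 190.2, 188.97, 186.4 and 189.2 bp on positions with 2 or more fragments, and 186.2, 186.4, 186.8, 184.9, 186.6 and 187.2 bp without dense windows. Thinned, wild type and Brg1-/- at moderate digestion had 188.1 and 188.0 bp. With repeated fragments the differences from wild type at light digestion were -23.7 bp in Snf5-/-, now past its interval, and -23.9 bp in Brg1-/-, reversed; the spacings had SEs of 5.70 to 22.3 bp. At moderate digestion that of Brg1-/- was 0.0572 bp, 0.222 bp on positions with 2 or more fragments and, reversed, -0.0785 bp when thinned, but 2.03 bp on peaks 1 to 4 and 2.32 bp without dense windows. That of Snf5-/- turned to 1.57 bp on peaks 1 to 4 and 1.69 bp without dense windows. Differences within their intervals under both settings also changed sign: Snf5-/- at light digestion had 0.382 bp on peaks 1 to 4 and 0.209 bp without dense windows, and at moderate digestion 8.15 bp with repeated fragments. Brg1-/- at light digestion had -15.1 bp on positions with 2 or more fragments, -0.0967 bp on fragment centres and -0.0294 bp when thinned. Of 12 array values 11 kept direction and side; Brg1-/- at moderate digestion missed it at 0.0103 with anchors picked in wild type, and had 0.0241 with pooled anchors.

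In windows enriched at light digestion, Snf5-/- over wild type at light digestion was 0.989 with repeated fragments and 0.994 with 500 bp windows, weaker, and 1.01 when thinned, reversed. At moderate digestion it was 0.986 with 2000 windows, reversed. Brg1-/- over Snf5-/- at light digestion was 1.01 with 50000 windows and 1.04 with 500 bp windows, now past its interval, and 0.991 with 2000 windows, reversed but within it. The other 53 of 60 values kept direction and side.

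Fragments of 160 to under 180 bp, mutant minus wild type at light digestion, differed by 5.83 (Snf5-/-) and 4.23 (Brg1-/-) percentage points with borders higher by 5 bp, and by 2.41 and, reversed, -0.683 with borders lower by 5 bp. At moderate digestion Snf5-/- had -0.300 and -1.08. Moderate minus light was -19.8 and -17.5 in wild type, -26.0 and -21.0 in Snf5-/- and -25.4 and -18.1 in Brg1-/-; with repeated fragments it was -26.0 in Snf5-/-. Segments nearly without fragments in wild type rose from 30 to 60 at a limit of 20%, and the other 5 values stayed within 1.5 times. With repeated fragments the windows near Smarcb1 and Smarca4 held 24.8% and 11.3%. Of the 6 Y chromosome values with repeated fragments, 3 moved beyond their intervals. Depth limits how many bins are called, as thinning lowered the count in all 4 contrasts.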

Other observations

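In this part, the tests of dense windows, anchors picked in wild type, single preparations, stacked windows and other splits of the libraries were chosen only after the result was seen.

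Chromosome 13 from 61900001 to 62000000 showed 3 levels of density that were kept across digestions: 13.2 and 14.0 FPM in wild type, 6.86 and 6.37 in Brg1-/- and 0.859 and 1.02 in Snf5-/-. Chromosome 4 from 121700001 to 121800000 also had 3 levels, in another order: 1.498 and 0.762 in wild type, 5.55 and 6.44 in Snf5-/- and 10.95 and 11.4 in Brg1-/-. On chromosome 12 from 116800001 the order was wild type, Snf5-/-, Brg1-/-, with 62.8 and 59.1, 37.2 and 42.5, and 16.9 and 16.4.

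Bins that differed more than 2-fold between genotypes may reflect differences in the DNA of the embryos, which came from a mixed strain background, and not in nucleosomes. Without error, such a difference would be of equal size at both digestions, a slope of 1. The bins were picked by the light value, so error in that value lowers the slope even for such a difference. In the contrasts with wild type that value includes the shallowest library. A genotype effect of equal size at both digestions would also give a slope of 1, so the slope cannot separate these causes. The slopes of moderate on light were 0.774 (95% interval 0.549 to 0.987) in Snf5-/- and 0.863 (0.666 to 1.05) in Brg1-/- against wild type. Between the mutants the slope was 0.906 (0.836 to 0.996). The sign was the same at both digestions in 79.5% of these bins in Snf5-/-, 100% in Brg1-/- and 100% between the mutants. Beforehand at least 0.8 in both mutants against wild type had been set for such a cause and less than 0.5 in either against it. Snf5-/- lay between. Without the 10 fullest 1 kb windows of each bin, at least 0.5 of the difference was kept in 82.8% of the 64 such bins of Snf5-/- (exact 95% interval 71.3% to 91.1%), 84.4% of the 64 of Brg1-/- (73.1% to 92.2%) and 89.3% of the 28 between the mutants (71.8% to 97.7%). Chromosome 7 from 22200001 (Snf5-/-) and chromosome 8 from 56200001 (Brg1-/-) had 0 fragments left in either genotype compared. They counted as kept only through a constant added to each count, which pulls sparse bins below wild type. The shares may therefore be too high for sparse bins lower than wild type. For bins with fragments left, they argue against stacked fragments in most of the bins. By this count 24 of these differences lost more, and 1 bin did so beyond counting error, chromosome 9 from 123800001, named after its values were seen. There Snf5-/- against Brg1-/- went from -1.43 to 0.17 on the log2 scale. DNA differences and the genotype itself stay open.

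The sharper arrays in both mutants were weighed against depth and fragment lengths, dense windows and the single preparations. With libraries drawn to 1 depth and 1 length distribution, the smallest of the 4 differences from wild type was still 5.59 standard errors above 0. Without windows above 2 times the mean density, the smallest difference of the first peak was 7.62 standard errors. With anchors picked in wild type, the Brg1-/- difference at moderate digestion was 0.0103 (95% interval -0.00252 to 0.0230), so there the choice of anchors stays open for the first neighbour, while neighbours 2 to 5 were sharper by 0.0189 (SE 0.00317). With 1 library per group, a difference between preparations cannot be told apart from the genotype, which stays open as a hypothesis.

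The digestion contrast called 604 bins, and the highest of the other splits of the 6 libraries into 3 and 3 called 23. Of the 10 splits 1, the real one, gave as many. In 6 of the others both libraries of a genotype fall on one side, so they test the digestion difference of 1 genotype, as 3 pairs of equal fits. That leaves 3 others that divide every genotype as the real one does, and the splits are too few for a share under 0.05.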
